A study of Mus musculus with 8 samples.

How the data were processed

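Expression was profiled on Illumina mouse bead arrays in 8 samples of sorted adipose progenitors, 4 of the CD9high and 4 of the CD9low fraction. Samples were assigned to fractions from their titles and cell type labels, which name the same fraction for each sample. For the CD9low samples another label field names high CD9 expression, and the gate text in the series design gives the CD9high gate for both fractions; the titles were followed. The slide and position of each array were read from the labels. Per the labels' protocols, epididymal fat was digested with collagenase, cells were sorted by flow cytometry, and total RNA was amplified with the Ovation Pico WTA System V2 and labelled with the Encore BiotinIL module. Amplification of small amounts of RNA can distort the ratios between transcripts and adds noise for dim genes.

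The authors deposited a table of signal intensity for 45281 probes that, per the file headers, also gives a detection p-value for each probe on each array. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited intensity values were not normalized between arrays: their medians ran from 5.03 (CD9low replicate 2) to 10.5 (CD9high replicate 4). A background had already been subtracted from them, since values within 0.5 of 0 had a median detection p of 0.434 and the lowest signals were negative. The detection p-values, as deposited, are multiples of a step that implies 936 negative control beads. A second deposited table of intensity values had nearly the same distribution on every array and the rank order of the matching signal column (Spearman correlation 1.0), with medians of 9.07 to 9.20. It was therefore read as linear, quantile normalized values with the direction of the signals, and was used only as an alternative. Whether anything else was done to make it is not given in the sources used here.

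Gene names came from the platform annotation paired with the probes. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none and are unnamed here; the named probes covered 19057 genes. Symbols were checked through the gene identifier against a table of RefSeq genes of assembly GRCm38.p6, which held 34807 of the probes' identifiers, and 0 symbols needed an update. No build is named for the probes, so that no coordinates are given. Probe sequences were not checked here against near-identical gene copies.

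Signals were processed with limma 3.58.1 in R 4.3.3. The neqc function fitted the normexp background model with the negative controls inferred from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Because the deposited signals were already background-subtracted, this second background step acts on subtracted values. The offset and the model compress the differences of dim probes, so fold changes of dim genes are understated. Probes entered the tests if their detection p was under 0.05 on at least 4 of 8 arrays, and a gene was represented by its tested probe with the highest mean over all arrays. This left 18085 named probes of 10724 genes. The depth of an array is its signal over background: between 41.1% (CD9low replicate 2) and 51.1% (CD9low replicate 3) of probes were detected, and the 4 arrays per fraction limit the precision.

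CD9high was compared with CD9low by lmFit and eBayes with no block, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Cd9 was also tested by an exact two-sided permutation of its 8 values. Where a gene was not above background on any array of a fraction, the fold is a bound: the mean of the brighter fraction against the mean, over the arrays of the dimmer fraction, of the higher of the lowest signal above background and the gene's own signal, on the normalized log2 scale. Gene lists (26) and lists of cell type markers (10) were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. They hold 732 genes, of which 669 had a named probe and 536 were measured. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists tested, and again with the correlation estimated from the data (statmod 1.5.0). Lists share members: for example, 11 of the 16 committed preadipocyte markers and 8 of the 21 interstitial progenitor markers stand on another list too. Named genes are Cd9 and the other gate genes, the 12 largest increases and 12 largest decreases among genes past the test with no overlap between fractions and a proper gene symbol, and in each list described the 4 members with the smallest p and any other member needed to state a count of 5 or fewer. A gene that 2 parts of this rule name counts under both.

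The alternatives were no background correction (quantile normalization of log2 of signal plus 16), centring of each array on its median, an offset of 50, the authors' normalized values, no filter or a detection p under 0.01, the mean of a gene's probes, the replicate number or the slide as a block, slide 1 alone, eBayes with trend and robust options, array weights, a fold threshold, the estimated correlation, and leaving out each array in turn with normalized values and tested genes kept. The analysis without replicate 2 of both fractions was chosen after seeing the data. Code was tested on simulated data for the 10724 genes of this comparison, with 200 genes changed in each of 20 runs. It recovered 20.8% of genes changed by a log2 fold change of 1 and 92.4% of those changed by 2, with 4.79% of called genes false. A list moved by 1 was called in 20 of 20 runs, and 0 other lists were called. Simulated genes varied independently, with no correlation between them and no deviant array. In the data, the correlation estimated for the members of a list was as high as 0.647 (macrophage and monocyte markers). These rates therefore do not give the share of false calls in the data. Figures were drawn with matplotlib 3.10.9.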

Results

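Gene expression was measured in adipose progenitors of lean C3H/HeOuJ mice aged 3 months. The cells came from the stromal vascular fraction of epididymal white adipose tissue, that is, the cells left after collagenase has released the fat-laden adipocytes. Progenitors were sorted as cells lacking the leukocyte marker CD45 and the endothelial marker CD31 and carrying the stromal proteins Gp38 (podoplanin) and PDGFRα. They were collected as 2 fractions by surface CD9, a tetraspanin membrane protein. Each fraction, CD9high and CD9low, was represented by 4 samples, each on its own array. The arrays carried 45281 probes, of which between 18618 (CD9low replicate 2) and 23121 (CD9low replicate 3) gave a signal above background at a detection p under 0.05. Values below are normalized log2 intensities, given as mean ± SD with n = 4 per fraction. Differences are log2 fold changes of CD9high over CD9low with their standard error (SE). The labels do not say whether samples came from separate animals or pools, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

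The sort marker was read first as a check of the labels, and its difference is no finding. Cd9 stood at 8.44 ± 0.14 in CD9high and 4.80 ± 0.52 in CD9low, a log2 fold change of 3.63 (SE 0.28, adjusted p = 0.000187). All 4 CD9high arrays lay above all 4 CD9low arrays, and the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays can give. The probe was above background on 4 of 4 CD9high and 2 of 4 CD9low arrays. Genes of the proteins shared by both gates did not pass the test. Pdgfra stood at 11.22 ± 0.25 in CD9high and 11.13 ± 0.23 in CD9low, a difference of 0.10 (SE 0.23, adjusted p = 0.910). Pdpn, which encodes Gp38, stood at 11.03 ± 0.16 and 11.08 ± 0.15, a difference of -0.05 (SE 0.20, adjusted p = 0.953). Ptprc, which encodes CD45, differed by -0.18 (SE 0.47, adjusted p = 0.920) and Pecam1, which encodes CD31, by -0.40 (SE 0.47, adjusted p = 0.804).

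The comparison of the fractions asks which genes differ between progenitors with high and low surface CD9. The largest increases in CD9high included genes of secreted matrix proteins. Col8a1, which encodes a chain of the network-forming type VIII collagen, stood at 11.56 ± 0.14 in CD9high against 7.69 ± 0.21 in CD9low, a log2 fold change of 3.87 (SE 0.21, adjusted p = 2.4e-05) or 14.6-fold. Cilp, a cartilage matrix protein gene, rose by 3.80 (SE 0.37, adjusted p = 0.000844), and Mfap4, whose product binds elastic microfibrils, rose by 3.72 (SE 0.27, adjusted p = 0.000146). Tgfbi, a matrix protein gene named for its induction by TGF-beta, rose by 2.91 (SE 0.39, adjusted p = 0.00528). Ccn5, of the matricellular CCN family, rose by 2.96 (SE 0.28, adjusted p = 0.000844). Itgbl1, an integrin-beta-like gene, rose by 3.04 (SE 0.30, adjusted p = 0.000844). The other named increases were Ackr4, which encodes a chemokine scavenger receptor (3.48), the LIM-domain gene Fhl2 (3.34), Plcxd3 (3.16), Rtl3 (2.87) and Fam180a. In CD9low, Ccn5, Plcxd3 and Rtl3 were each above background on only 2 of 4 arrays. For Fam180a the CD9low arrays were all not above background, so that only a bound can be given: it was at least 8.84-fold higher in CD9high (adjusted p = 8.47e-05). Such bounds set the mean of the bright fraction against the dimmest detected signal on the arrays of the dim fraction. With Cd9 these genes make up the 12 largest increases, and each of the 12 passed the test in all 21 alternative analyses.

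Of the 12 largest decreases in CD9high, Vtn, which encodes the adhesive glycoprotein vitronectin, stood at 7.44 ± 0.83 in CD9high and 10.47 ± 0.25 in CD9low, a log2 fold change of -3.04 (SE 0.38, adjusted p = 0.00322). Cnmd, which encodes chondromodulin, changed by -2.98 (SE 0.29, adjusted p = 0.000844) and was above background on 1 of 4 CD9high arrays. Acer2, an alkaline ceramidase gene, changed by -2.77 (SE 0.31, adjusted p = 0.00161), and Megf10, an engulfment receptor gene, by -2.47 (SE 0.26, adjusted p = 0.00147). Cmbl changed by -2.07 (SE 0.23, adjusted p = 0.00161). Blnk, an adaptor gene best known from B cells, was not above background on any CD9high array and at least 3.33-fold higher in CD9low (adjusted p = 0.00164). These 6 genes passed the test in all 21 alternatives. The remaining 6 of the 12 largest decreases were Gsc, a homeobox gene (-2.86, adjusted p = 0.0107), Slc1a3, a glutamate transporter gene (-2.51, adjusted p = 0.0124), Reep6 (-2.52, adjusted p = 0.0227), Ret, a receptor tyrosine kinase gene (-2.45, adjusted p = 0.0261), Pcdh12, a protocadherin gene (-1.99, adjusted p = 0.0308) and Rxfp2, a relaxin-family peptide receptor gene (-2.21, adjusted p = 0.0410). Without the filter on dim probes all 6 missed the threshold, with adjusted p of 0.0509, 0.0575, 0.0978, 0.109, 0.105 and 0.149 in the order named. On slide 1 alone Gsc (0.0536), Slc1a3 (0.0717), Reep6 (0.153) and Rxfp2 (0.140) missed it. Slc1a3 also missed it without CD9high replicate 1 (adjusted p = 0.0587), and Reep6, Ret, Pcdh12 and Rxfp2 each without several single arrays, with adjusted p of up to 0.0790, 0.101, 0.115 and 0.125. Further losses included those of Pcdh12 with median centring (0.0510), Rxfp2 with an offset of 50 (0.0588) or the slide as a block (0.0589), and Ret (0.0736) and Pcdh12 (0.0632) without replicate 2 of both fractions.

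**Figure D1:**
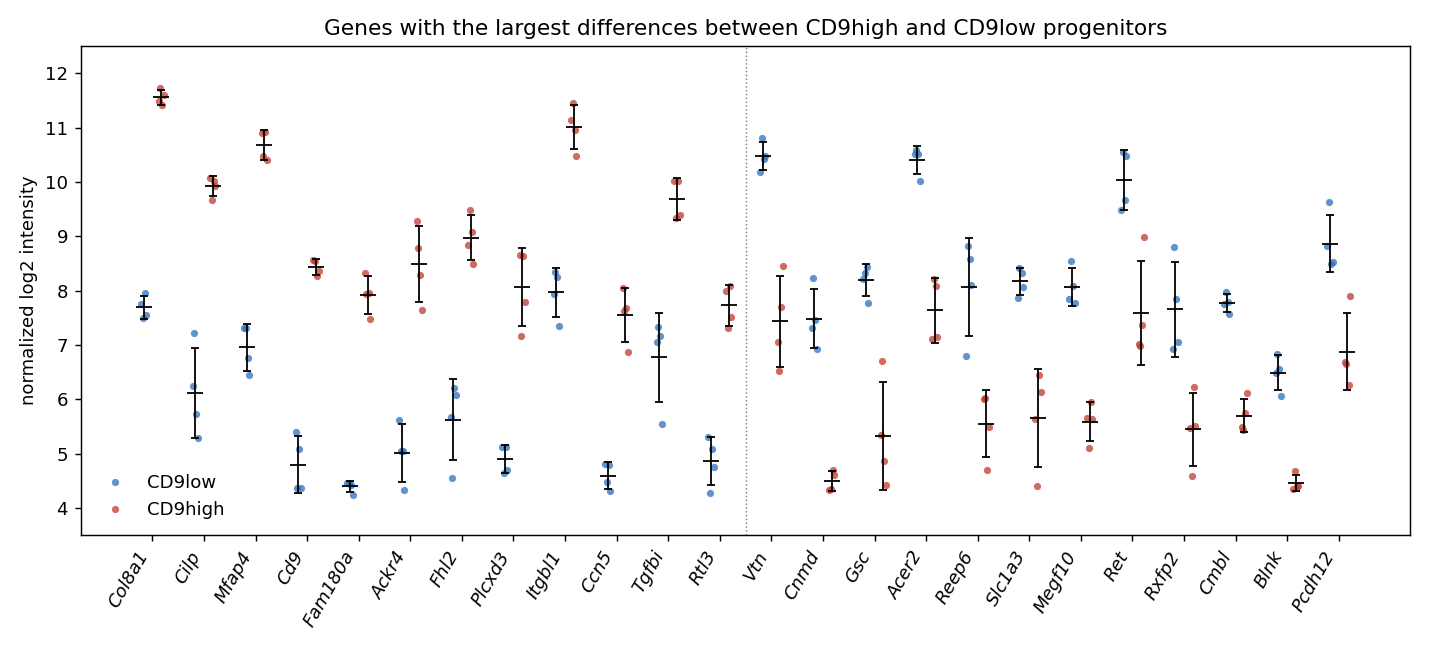
Normalized log2 intensity (y axis) of the 12 genes with the largest increase and the 12 with the largest decrease in CD9high (x axis, separated by the dotted line); each point is 1 array, blue for CD9low and red for CD9high, the dash is the mean and the bars are the SD of 4 arrays. In each gene shown the 4 CD9high points lie wholly to one side of the 4 CD9low points, as for Col8a1 with means of 11.56 and 7.69.

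In all, 181 of 10724 genes tested (1.69%) passed an adjusted p of 0.05, 121 higher and 60 lower in CD9high, and 1143 had an unadjusted p under 0.05. All but 1 of the 181 changed by at least 1 on the log2 scale. No array of one fraction overlapped the other for 825 genes (7.69%, where chance gives 2.86%), including each of the 181. Of 75 called genes with several tested probes, 30 had at least 2 probes past the test on their own, and 0 had probes called in opposite directions. The counts depend on single arrays: they fell to 36 higher and 18 lower without CD9high replicate 1, 52 and 23 without CD9low replicate 1, 51 and 21 without CD9high replicate 3, 56 and 25 without CD9low replicate 3, and 56 and 20 without CD9low replicate 4. Without CD9high replicate 2 they were 87 and 39, without CD9high replicate 4 they were 78 and 38, and without CD9low replicate 2 they were 158 and 72. With the replicate number, which the fractions share, as a block, 56 genes were higher and 20 lower.

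**Figure D2:**
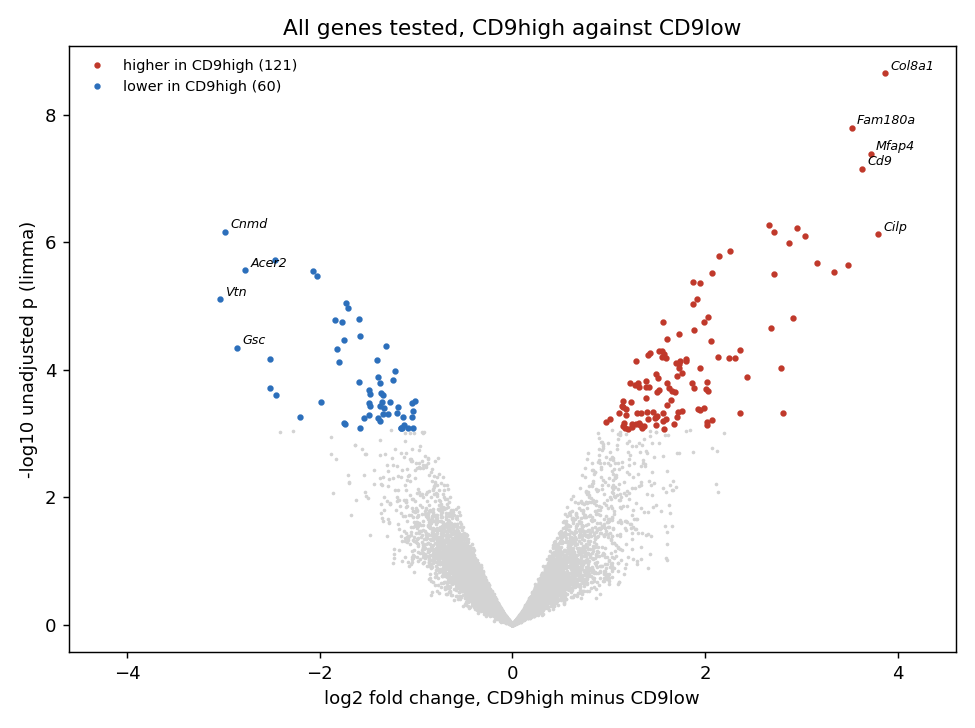
Log2 fold change of CD9high over CD9low (x axis) against -log10 of the unadjusted limma p (y axis) for 10724 genes; red points are the 121 genes higher and blue points the 60 genes lower in CD9high at an adjusted p under 0.05, and grey points did not pass. Col8a1, Fam180a, Mfap4, Cd9 and Cilp lie farthest to the upper right, and Vtn and Cnmd farthest to the left among the called genes.

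The 8 arrays lay on 2 slides, replicates 1 to 3 of both fractions on slide 1 and replicate 4 of both on slide 2. With the slide as a block, 99 genes were higher and 42 lower, and on slide 1 alone 35 and 13. On slide 2, 1 array per fraction allows no test. In a count added after the data were seen, 47 of the 48 genes called on slide 1 alone differed in the same direction on slide 2, against 53.4% of all tested genes. The median difference of the genes called higher over all 8 arrays was 1.70 on slide 1 and 1.64 on slide 2, and that of the genes called lower was -1.52 and -1.34; the choice of these genes on all arrays fixes their direction on both slides. Between the slides, with the fraction in the model, 0 genes passed the test.

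Lists of genes fixed before the data were examined were then compared between the fractions, with camera run at its preset correlation of 0.01 and adjusted over 33 lists. Of these, 7 were higher and 3 lower in CD9high; 4 and 0 held with a correlation estimated from the data. Of the 53 named genes past the test, 19 passed in every alternative; those on the lists were Col8a1, Cilp, Mfap4, Tgfbi, Ccn5 and Sfrp4. Named genes that missed the threshold in at least 11 of the 21 alternatives were Tgfb3 (15), Plin2, Dkk3, Fbln1 and Thbs2 (13 each), Fap, Fgf1 and Rxfp2 (12 each) and Ccn2, Ly6c1, Ndrg1 and Pdgfc (11 each). Without CD9high replicate 1, 33 of the 53 missed the threshold, with adjusted p from 0.0542 to 0.157. The numbers lost without CD9low replicate 1, CD9high replicate 2, CD9high replicate 3, CD9low replicate 3, CD9high replicate 4 and CD9low replicate 4 were 23, 18, 27, 25, 20 and 27. Without CD9low replicate 2, 0 were lost. Blocking by replicate number lost 28 of the 53 (adjusted p 0.0511 to 0.148). Among them were Eln, Lpl, Cxcl14, S100a4, C7, Col14a1 and Hsd11b1. The p-values given for single genes are those without this block, and a pairing of the samples by number cannot be set aside.

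Early interstitial progenitor markers, a set that marks Dpp4 and Pi16 positive fibroblast-like progenitors of adipose tissue, were higher in CD9high. Of 21 measured, 6 rose, 0 fell and 15 did not pass the test, and adjusted over the list alone 17 rose. Their median log2 fold change was 1.14 with 20 of 21 above 0 (adjusted p = 4.02e-19, and adjusted p = 0.0107 with an estimated correlation). Il33, an alarmin cytokine gene, rose by 2.25 (SE 0.35, adjusted p = 0.0124) and Dpp4, a membrane dipeptidase gene, by 1.60 (SE 0.25, adjusted p = 0.0124). Cd55, a complement regulator gene, rose by 1.49 (SE 0.25, adjusted p = 0.0172), Sema3c, a secreted semaphorin gene, by 1.60 (SE 0.28) and Efhd1 by 1.69 (SE 0.31). Ly6c1 rose by 1.49 (SE 0.31); whether its probe also reads the near-identical Ly6c2 was not checked. Without CD9high replicate 1 all 6 genes missed the threshold, and with the replicate number as a block all but Efhd1 did. The list itself passed in all 22 alternatives. Its median was 1.33 on slide 1 and 1.43 on slide 2.

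Committed preadipocyte markers, the set of the Icam1 positive state nearer to adipocytes, were lower in CD9high. Of 16 measured, 3 fell, 1 rose and 12 did not pass, with a median of -0.57 (adjusted p = 0.0416, lost with an estimated correlation, adjusted p = 0.480). Adjusted over the list alone 5 fell and 2 rose. The call was also lost on slide 1 alone (adjusted p = 0.206), with median centring (adjusted p = 0.0572), and without CD9low replicate 1 (adjusted p = 0.278), CD9low replicate 3 (0.195), CD9high replicate 4 (0.153) or CD9low replicate 4 (0.0732). Pparg, the nuclear receptor that drives adipocyte differentiation, changed by -1.59 (SE 0.28, adjusted p = 0.0204), from 8.76 ± 0.25 in CD9low to 7.18 ± 0.48 in CD9high. The chemokine gene Cxcl14 changed by -1.47 (SE 0.27, adjusted p = 0.0255) and Lpl, which encodes lipoprotein lipase, by -1.01 (SE 0.19, adjusted p = 0.0307). Mgp, which encodes matrix Gla protein, an inhibitor of calcification, went the other way and rose by 2.43 (SE 0.42, adjusted p = 0.0186). Icam1, the marker that names this state, also differed the other way, by 0.69 (SE 0.24, adjusted p = 0.287). Its fractions did not overlap. In all, 6 of the 16 markers were above 0. The median was -0.53 on slide 1 and -0.72 on slide 2.

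Adipocyte and lipid storage genes were also lower in CD9high, with a median of -0.38 (adjusted p = 0.0138, lost with an estimated correlation, adjusted p = 0.415). Of 19 measured, 2 fell, 0 rose and 17 did not pass; adjusted over the list alone, 2 fell. The falling genes were Lpl and the lipid droplet gene Plin2, which changed by -1.58 (SE 0.34, adjusted p = 0.0495), a call lost in 13 of 21 alternatives, among them no background correction and the authors' normalized values. Fabp4, a fatty acid binding protein gene, differed by -0.72 (SE 0.29, adjusted p = 0.395). The call was also lost without CD9low replicate 3 (adjusted p = 0.0707) or CD9high replicate 4 (adjusted p = 0.167). The median was -0.50 on slide 1 and -0.31 on slide 2. Adipogenic transcription regulators did not pass as a list (median -0.11, adjusted p = 0.921). Of 20 measured, 1 rose and 1 fell, and over the list alone 1 rose and 2 fell. Pparg fell, and Gata2, a factor that restrains adipogenesis, rose by 1.72 (SE 0.35, adjusted p = 0.0379).

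Among matrix genes, the glycoproteins and proteoglycans were higher in CD9high. Of 25 measured, 5 rose, 0 fell and 20 did not pass, with a median of 0.31 (adjusted p = 5.82e-07, and adjusted p = 0.0445 with an estimated correlation). Adjusted over the list alone 8 rose. Beside Mfap4 and Cilp, Eln, which encodes elastin, rose by 1.76 (SE 0.30, adjusted p = 0.0167). Thbs2, a thrombospondin gene, rose by 2.02 (SE 0.43, adjusted p = 0.0467) and Fbln1, a fibulin gene, by 0.97 (SE 0.20, adjusted p = 0.0453), and both calls were lost in 13 of 21 alternatives. The median was 0.31 on slide 1 and 0.36 on slide 2. Fibrillar and fibril-associated collagens did not pass as a list (adjusted p = 0.100), and among the alternatives passed only without CD9high replicate 2 (adjusted p = 0.0177). Of 11 measured, 2 rose and 0 fell, and over the list alone 3 rose. Col8a1, which is on the list as fixed although type VIII collagen forms networks, rose, as did Col14a1, by 1.63 (SE 0.29, adjusted p = 0.0227), while Col16a1 differed by 1.19 (SE 0.27, adjusted p = 0.0541). The median of this list was -0.05 although its mean was 0.47. The 17 basement membrane genes (median -0.29, adjusted p = 0.496), the 17 collagen processing genes (0.03, adjusted p = 0.511) and the 18 matrix proteases and inhibitors (-0.03, adjusted p = 0.966) held 0 members past the test. Adjusted over the list alone, 1 basement membrane gene, Col4a6, was higher (1.05, SE 0.27).

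Genes of the TGF-beta pathway and response were higher in CD9high. Of 18 measured, 3 rose, 0 fell and 15 did not pass, with a median of 0.39 (adjusted p = 0.000524, and adjusted p = 0.0445 with an estimated correlation); over the list alone 6 rose. Tgfbi rose as given above. Ccn2, a matricellular gene known as a TGF-beta target, rose by 2.37 (SE 0.48, adjusted p = 0.0379), and the ligand gene Tgfb3 by 1.35 (SE 0.29, adjusted p = 0.0495), a call lost in 15 of 21 alternatives, among them no background correction, median centring and the authors' normalized values. Pmepa1, a feedback inhibitor of the pathway, differed by 1.80 (SE 0.40, adjusted p = 0.0525). The median was 0.38 on slide 1 and 0.51 on slide 2. Contractile and myofibroblast genes did not pass as a list (median 0.24, adjusted p = 0.250). Of 14 measured, 1 rose and 1 fell, and over the list alone the counts were again 1 and 1. S100a4, a calcium-binding protein gene, rose by 2.02 (SE 0.35, adjusted p = 0.0204), and Fap, which encodes fibroblast activation protein, changed by -1.33 (SE 0.26, adjusted p = 0.0349).

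BMP, Wnt and Hedgehog genes were higher in CD9high. Of 28 measured, 4 rose, 0 fell and 24 did not pass, with a median of 0.72 (adjusted p = 2.31e-08, and adjusted p = 0.0107 with an estimated correlation). Over the list alone 12 rose. Sfrp4, a secreted Wnt antagonist gene, rose by 2.71 (SE 0.31, adjusted p = 0.00162). Wnt10b, a Wnt ligand gene, rose by 2.36 (SE 0.36, adjusted p = 0.0111) and Dkk3, of the Dickkopf family, by 2.02 (SE 0.43, adjusted p = 0.0457, lost in 13 of 21 alternatives), beside Ccn5. In CD9low, Dkk3 was above background on 1 of 4 arrays, and Wnt10b and Ccn5 each on 2 of 4. The median was 0.85 on slide 1 and 0.52 on slide 2. PDGF, FGF and EGF family genes were higher with a median of 0.19 (adjusted p = 0.0216). The call was lost with an estimated correlation (adjusted p = 0.162) and without CD9low replicate 2 (adjusted p = 0.0989). Of 22 measured, 2 rose, 0 fell and 20 did not pass; over the list alone 6 rose and 2 fell. Fgf1 rose by 1.60 (SE 0.31, adjusted p = 0.0336) and Pdgfc by 1.14 (SE 0.22, adjusted p = 0.0342). Pdgfc was above background on only 1 of 4 CD9low arrays. Fgf10 differed by -1.88 on its brightest probe (SE 0.47, adjusted p = 0.0885). However, 2 of its 3 tested probes passed on their own, and with the mean of its probes it passed as lower (adjusted p = 0.00551). The median was 0.24 on slide 1 and 0.03 on slide 2.

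**Figure D3:**
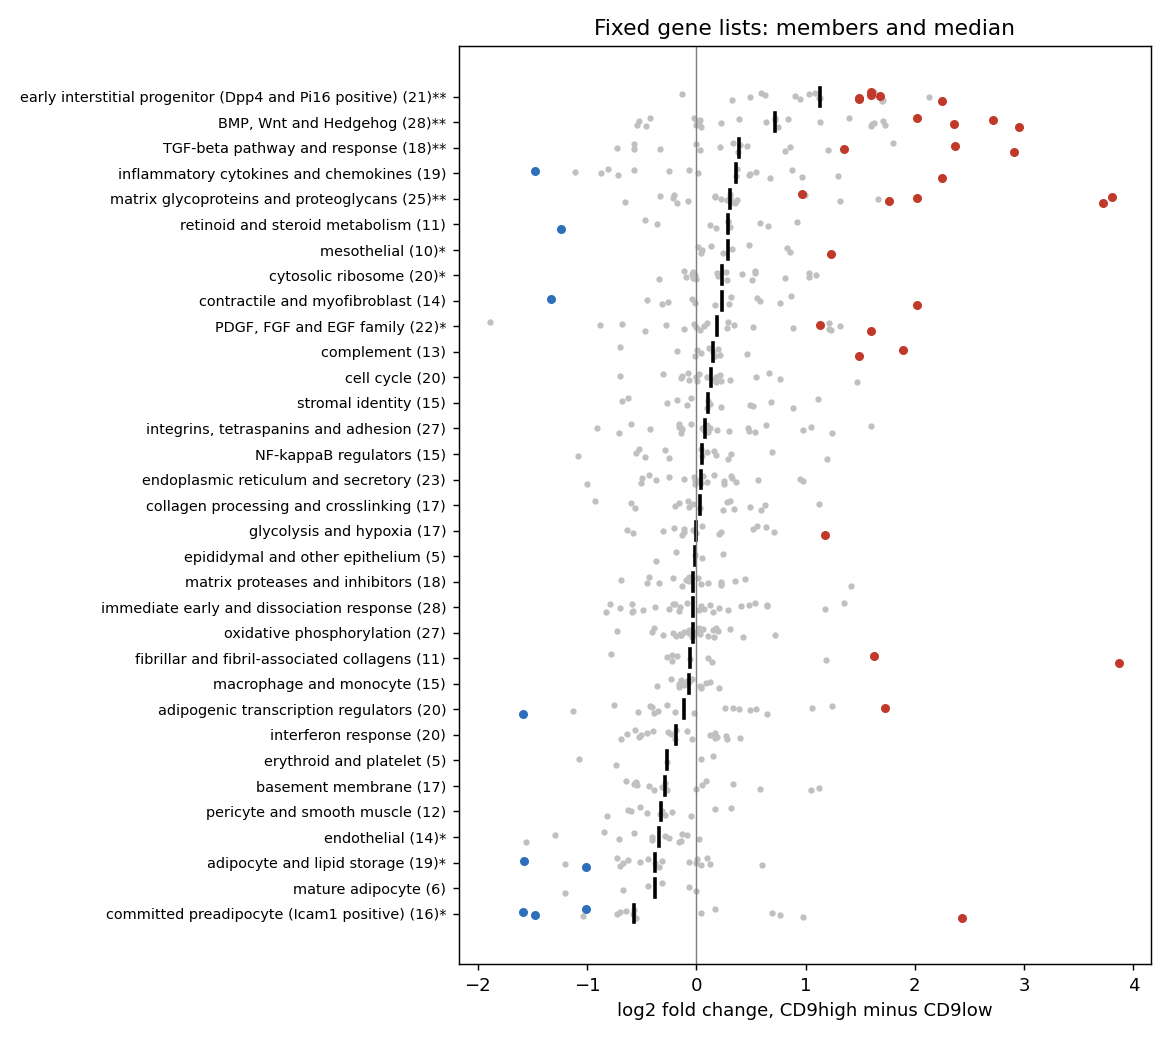
Log2 fold change of CD9high over CD9low (x axis) of the members of each tested list (rows, with the number measured in parentheses); each point is 1 gene, red if called higher, blue if called lower and grey otherwise, and the black bar is the median. A star marks the lists past the test with the preset correlation and 2 stars those that also passed with an estimated correlation; the highest median is that of the early interstitial progenitor list (1.14) and the lowest that of the committed preadipocyte list (-0.57).

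Inflammatory, complement and immune response genes did not pass as lists. Of 19 inflammatory cytokines and chemokines, Il33 rose and Cxcl14 fell (median 0.37, adjusted p = 0.921); over the list alone 1 rose and 4 fell, among them the chemokine gene Ccl11 (-0.71, SE 0.21, adjusted p over all genes 0.177). Of 13 complement genes, Cd55 and C7 rose, C7 by 1.89 (SE 0.34, adjusted p = 0.0227), and over the list alone the count was also 2. The complement list had a median of 0.16 and an adjusted p of 0.0536, and passed in 11 of 22 alternatives. The 15 NF-kappaB regulators (median 0.05, adjusted p = 0.873) and the 20 interferon response genes (-0.19, adjusted p = 0.448) held 0 members past the test, over the list alone included.

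Adhesion and metabolism lists did not pass the test, apart from the ribosome list. The 27 integrins, tetraspanins and adhesion genes had a median of 0.08 (adjusted p = 0.200) and 0 members past the test; over the list alone 1, Cdh13, was higher (1.24, SE 0.29). Among 11 retinoid and steroid metabolism genes (median 0.29, adjusted p = 0.344), Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid, changed by -1.24 (SE 0.21, adjusted p = 0.0200), and over the list alone Rbp4 was higher (0.92, SE 0.21). Among 17 glycolysis and hypoxia genes (median -0.001, adjusted p = 0.359), Ndrg1 rose by 1.18 (SE 0.23, adjusted p = 0.0361), and it was also the 1 gene past the test over the list alone. The 20 cell cycle genes (median 0.13, adjusted p = 0.225), 28 immediate early and dissociation response genes (-0.03, adjusted p = 0.980), 27 oxidative phosphorylation genes (-0.03, adjusted p = 0.980), 23 endoplasmic reticulum and secretory genes (0.04, adjusted p = 0.866) and 15 stromal identity genes (0.11, adjusted p = 0.344) held 0 members past the test. Over the list alone, Rrm2 of the cell cycle list (1.47, SE 0.37) and Pdgfrl of the stromal list (0.89, SE 0.20) were higher. The cell cycle list passed with no filter on dim probes (adjusted p = 0.012) and without replicate 2 of both fractions (0.0459). Genes of the cytosolic ribosome were higher as a list, with a median of 0.24 over 20 genes and 0 members past the test, over the list alone included (adjusted p = 0.0416; adjusted p = 0.415 with an estimated correlation). On CD9low replicate 2 the mean of this list was 9.79, against 10.41 to 10.52 on the other CD9low arrays, and without that array the list did not pass (adjusted p = 0.0993). It also failed on slide 1 alone (0.126), with median centring (0.0995) and without CD9high replicate 1 (0.0989), CD9high replicate 3 (0.0897), CD9high replicate 4 (0.144) or CD9low replicate 4 (0.0528). Its median was 0.26 on slide 1 and 0.20 on slide 2. In 8 lists the median, the mean and the direction of the test differed in sign: fibrillar collagens, matrix proteases, adipogenic regulators, NF-kappaB regulators, immediate early genes, oxidative phosphorylation, glycolysis and macrophage markers.

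Markers of other cell types were read as a check on the sort. The 10 mesothelial markers were higher in CD9high, 10 of 10 above 0 with a median of 0.29 (adjusted p = 0.00915; adjusted p = 0.338 with an estimated correlation). The matrix glycoprotein, TGF-beta, BMP, Wnt and Hedgehog and interstitial progenitor lists were higher too. Whether these lists vary together across arrays was not tested. Igfbp5 alone rose among them, by 1.23 (SE 0.24, adjusted p = 0.0308), and over the list alone Rspo1 was also higher (0.83, SE 0.23). The list's median was 0.15 on slide 1, where it did not pass (adjusted p = 0.206), and 0.91 on slide 2; it also failed without CD9high replicate 4 (adjusted p = 0.0830) or CD9low replicate 4 (0.0523). The 14 endothelial markers were lower in CD9high, as were the adipocyte and preadipocyte lists. Their median was -0.34, with 1 of 14 above 0 (adjusted p = 0.0388, and adjusted p = 0.480 with an estimated correlation). None passed over all genes, and over the list alone Plvap (-1.55, SE 0.38) and Sox17 (-1.29, SE 0.35) were lower. The endothelial call was lost with array weights (adjusted p = 0.116) and without CD9high replicate 1 (0.0914), CD9low replicate 2 (0.146), CD9low replicate 3 (0.219), CD9high replicate 4 (0.167) or replicate 2 of both fractions (0.0674), and its median was -0.50 on slide 1 and 0.06 on slide 2.

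Other marker lists did not pass: 12 pericyte and smooth muscle markers (median -0.33, adjusted p = 0.102), 6 mature adipocyte markers (-0.38, adjusted p = 0.102), 5 epithelial markers (-0.01, adjusted p = 0.980) and 5 erythroid and platelet markers (-0.27, adjusted p = 0.304). The pericyte list passed with no filter on dim probes (adjusted p = 0.0451), with the replicate number as a block (0.0465) and without CD9high replicate 3 (0.0433). The mature adipocyte list passed without CD9high replicate 1 (adjusted p = 0.0211) or CD9high replicate 2 (0.028). Lymphocyte and Schwann cell markers, with 4 measured each, and skeletal muscle markers, with 1, were too few to test. The 15 macrophage and monocyte markers did not differ past the test between the fractions (median -0.06, adjusted p = 0.921) but varied between arrays. Their mean was 7.71 on CD9low replicate 2 and 7.68 on CD9high replicate 2, against 5.40 on CD9low replicate 4 and 5.58 on CD9high replicate 4; the other 4 arrays lay between 6.60 and 6.99. Cd163, a scavenger receptor gene of macrophages, stood at 10.88 and 10.62 on the replicate 2 arrays and at 5.22 and 6.59 on the replicate 4 arrays of CD9low and CD9high. The gate excluded CD45 positive cells. Without replicate 2 of both fractions, an analysis added after the data were seen, 190 genes were higher and 80 lower in CD9high, of which 109 and 45 were among the 121 and 60.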

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

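Of the tests in this part, those of macrophage, mesothelial and endothelial markers and the counts of splits within replicate numbers and for single lists were chosen only after the result was seen; the counts of all splits for the numbers of genes and lists and the test of probe pairs were set beforehand. The number of genes past the test between CD9high and CD9low was set against the other ways to split the 8 arrays into 4 and 4. The real split gave 181 genes and the highest other split 0, so 1 of 35 splits gave as many, and chance can be excluded for this count only if arrays may be exchanged freely. Some same-numbered arrays were alike in Lcn8 and macrophage markers, and the 8 splits that exchange arrays only within a number are too few to give a share under 0.05 (real 181, highest other 0). For the fixed lists, the real split gave 10 past the test and the highest other split 12, and 4 of 35 splits gave as many, so that chance cannot be excluded for the number of lists. The 3 other splits with as many each set 3 arrays of a fraction with 1 of the other on a side, and so keep part of the real contrast. Splits with 2 arrays of each fraction on a side hold none of that contrast, and they gave up to 9 lists. Taken singly, 1 of 35 splits gave as small a p for the interstitial progenitor, BMP, Wnt and Hedgehog, matrix glycoprotein, TGF-beta and PDGF, FGF and EGF lists. For the other lists past the test the number was 3 (mesothelial), 4 (ribosome), 6 (adipocyte), 8 (committed preadipocyte) and 13 (endothelial). A correlation estimated from the data left 4 lists.

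CD9low replicate 2 stood apart from the other arrays. Its mean correlation with the other CD9low arrays was 0.863, against 0.931 to 0.932 for the other 3 (gap over range 0.986), and it had the fewest detected probes. Macrophages or monocytes in that sort were weighed as the source of most of its difference, since the 15 fixed markers, 0 of which stand on another list, had a median of 1.39 (bootstrap interval 0.729 to 2.09) above the other CD9low arrays, among them Lyz2 (10.5 against 8.37) and Laptm5 (11.1 against 8.70), although the gate removes CD45 positive cells. These markers deviated about as much on CD9high replicate 2 (1.31) and fell on CD9high replicate 4 (-1.57), each against the rest of its fraction. Deviations from the mean of the fraction were compared across 10724 genes. Those of CD9low replicate 2 correlated at -0.100 (bootstrap interval -0.121 to -0.080) with CD9high replicate 2 and at 0.265 (0.245 to 0.285) with CD9high replicate 4. Macrophages would give the opposite signs if they were also the main source of the deviations of those CD9high arrays. On that condition only, the values argue against this source. The 2 signs are not separate facts, since the deviations of the CD9high arrays sum to 0 for each gene. The lowest correlation, -0.143, was with CD9high replicate 1, where the markers deviated by only 0.4. Genes are not independent replicates, so these intervals are too narrow. A smaller part from macrophages stays open, as does a larger one where the condition fails. CD9high replicate 2 also had the lowest mean correlation of its fraction, 0.917. Uneven amplification or loss of RNA that strikes single probes remains open: deviations of 2 probes of the same gene correlated at 0.246 across 4642 genes (genes are not independent replicates), below 6 of the 7 other arrays but within their range of 0.210 to 0.343. The design names no biological difference for a single array, so none beyond macrophages was tested. Other cells in that sort therefore stay open. Of the endothelial markers, Cldn5 (11.18), Plvap (9.18) and Emcn (7.03) were highest on this array, while Sox17 was highest on CD9low replicate 3 (6.86). Pecam1 was highest here by its brighter probe (7.39) but not by its other tested probe (6.19). The stromal identity mean was the lowest of its fraction (9.22 against 9.82 to 9.87). Without this array 158 genes were higher and 72 lower.

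Markers of mesothelial and endothelial cells differed between CD9high and CD9low, and a larger share of such cells in a fraction was weighed as the source of the called genes, whose smallest changes were 0.97 and -1.01. For endothelial cells, which the CD31 gate removes, the 14 measured markers had a median of -0.343 (bootstrap interval -0.706 to -0.147), but dim markers understate a change. The 6 at or above the median level of all tested genes, 7.04, the brightest being Tek at a mean of 9.56, had a median of -0.365 with an interval of -1.20 to -0.135. Tek, which differed by -0.133, also stands on the early interstitial progenitor list, so its signal need not come from endothelial cells. For mesothelial cells, the 10 measured markers had a median of 0.287 (0.056 to 0.83), and the 4 at or above that level (Gpm6a, Igfbp5, Rspo1 and Slc9a3r1, the brightest being Igfbp5 at a mean of 9.36) one of 0.844 (0.018 to 1.23). Both intervals of the brighter markers, which are few, include the smallest change of a called gene. A larger share of either cell type therefore cannot be told apart from a difference between progenitors for the genes with small changes; 2 of the endothelial and 2 of the mesothelial markers stand on another list. A difference between the fractions themselves, which the design names, also stays open.

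Single arrays stood far from the other 3 of their fraction in 16 of 186 groups tested, where chance gives about 9.3; 5 were on CD9low replicate 2 and 4 on CD9high replicate 2. The measure is the gap to the nearest array over the whole range. CD9low replicate 4 was lowest for Fam180a (4.25 against 4.43 to 4.46, ratio 0.838, all not above background), Tgfbi (5.55 against 7.05 to 7.33, ratio 0.844) and Acer2 (10.02 against 10.51 to 10.58, ratio 0.881). S100a4 was lowest on CD9high replicate 3 (7.86 against 8.50 to 8.51, ratio 0.983). Gata2 (6.35 against 7.30 to 7.44, ratio 0.870) and Cxcl14 (8.50 against 9.38 to 9.48, ratio 0.892) were lowest on CD9high replicate 2. Hsd11b1 was highest on CD9low replicate 3 (12.20 against 12.08 to 12.09, ratio 0.911) and Igfbp5 on CD9low replicate 2 (9.26 against 8.53 to 8.60, ratio 0.904).

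List means on CD9low replicate 2 were lowest of their fraction for basement membrane (9.50 against 9.80 to 9.83, ratio 0.911), stromal identity (9.22 against 9.82 to 9.87, ratio 0.911) and cytosolic ribosome genes (9.79 against 10.41 to 10.52, ratio 0.856). Ribosome genes were also lowest on CD9high replicate 2 within its fraction (10.48 against 10.64 to 10.66, ratio 0.862). Cell cycle genes were highest on CD9high replicate 4 (7.49 against 6.59 to 6.72, ratio 0.851) and epithelial markers on CD9high replicate 1 (6.12 against 5.04 to 5.16, ratio 0.892). Of these markers, Lcn8 was high on replicate 1 of both fractions, 8.37 in CD9high and 8.85 in CD9low, against 4.39 to 5.14 on the other 6 arrays. CD9high replicate 2 had 19280 detected probes against 21508 to 21888 on the other CD9high arrays (ratio 0.854). Of 3445 tested probes that carry no gene name here, 34 passed the test between fractions, 23 higher and 11 lower in CD9high.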

How the results depend on the processing

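The analysis without replicate 2 of both fractions was chosen after the data were seen. Cd9 passed in all 21 alternatives (log2 fold change 2.60 to 3.83), and all 181 called genes kept their direction in every alternative that tested them. For these genes no array of one fraction overlapped the other. Leaving out, blocking or weighting arrays could therefore not turn their direction. Only the alternatives that change the values themselves put it to a test. Against 121 higher and 60 lower genes, array weights gave 275 and 147, slide 1 alone 35 and 13, and the analysis without replicate 2 of both fractions 190 and 80; median centring gave 35 lower genes. Leaving out 1 array gave 36 to 158 higher and 18 to 72 lower genes. Against 7 lists higher and 3 lower, an estimated correlation gave 4 and 0, and leaving out 1 array 0 to 4 lower lists. Fewer arrays, on slide 1 and in the left-out sets, reduce calls by construction, although leaving out CD9low replicate 2 raised them; for this and the other changes the cause was not tested. The labels do not say what the replicate numbers shared by the fractions mark. Same-numbered deviations correlated at 0.223, -0.100, 0.183 and 0.159, and 5 of 8 arrays correlated best with their own number. Lcn8 was high on replicate 1 of both fractions, and macrophage markers on replicate 2 of both. A pairing of the samples by number can therefore not be set aside. With the replicate number as a block, 56 genes were higher and 20 lower, 52 and 20 of them shared, and 28 of the 53 named genes past the test, among them Il33, Dpp4, Cd55, Eln, Slc1a3, Reep6, Pcdh12 and Rxfp2, missed it (adjusted p 0.0511 to 0.148). Over 157 named genes other than Cd9, 2940 of 3288 recomputed values kept their side of the threshold. Another 293 lost it, 55 gained it and 0 called ones turned. The losses all fell on the 52 of these genes past the test, since no other gene could lose it. Over the lists 675 of 725 values kept their side, 31 lost it and 19 gained it. Here too only lists past the test could lose it. Signal over background limits dim genes, of which 12 called ones had no CD9low array and 5 no CD9high array above it.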

Other observations

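The test of the balance of progenitor lists, and the genes named here, were chosen after their values were seen. Whether each of these genes passes in the 21 alternatives was not examined. Plin2 and Tgfb3, with the same adjusted p as Osmr below (0.0495), missed the threshold in 13 and 15 of them. Higher in CD9high were the homeobox genes En1 (log2 fold change 2.01, SE 0.36, adjusted p = 0.0228) and Hoxd8 (1.65, SE 0.31, adjusted p = 0.0301) and the odd-skipped family gene Osr2 (1.73, SE 0.28, adjusted p = 0.0133). Lower in CD9high were the Notch receptor gene Notch1 (-1.41, SE 0.22, adjusted p = 0.0125) and Heyl, a transcription factor gene known as a Notch target (-1.82, SE 0.28, adjusted p = 0.0111). The cytokine receptor genes Lifr and Osmr were lower as well, Lifr by a log2 fold change of -1.58 (SE 0.23, adjusted p = 0.00804) and Osmr of -1.08 (SE 0.23, adjusted p = 0.0495).

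The metalloprotease genes Adamts8 and Adamts19 were higher in CD9high, Adamts8 by 1.92 (SE 0.24, adjusted p = 0.00322) and Adamts19 by 2.04 (SE 0.27, adjusted p = 0.00528), although the fixed list of matrix proteases, which does not hold these genes, did not pass. Epyc, which encodes a small leucine-rich proteoglycan, was not above background on any CD9low array and at least 4.91-fold higher in CD9high (adjusted p = 0.000844). Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, was at least 2.79-fold higher (adjusted p = 0.00352). Lower in CD9high were the peptidase genes Enpep (-1.84, SE 0.25, adjusted p = 0.00540) and Pappa (-1.59, SE 0.21, adjusted p = 0.00534), and the fatty acid metabolism genes Ephx2 (-1.54, SE 0.32, adjusted p = 0.0410) and Abcd2 (-1.49, SE 0.27, adjusted p = 0.0234).

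A hypothesis is that the 2 fractions differ in the balance of the 2 progenitor programmes, with CD9high nearer to the early interstitial and CD9low nearer to the committed preadipocyte state. The mean of the interstitial list minus that of the committed list was -0.87 ± 0.22 on the CD9high and -2.32 ± 0.63 on the CD9low arrays (SD, n = 4 each), and each CD9high array, from -1.10 to -0.62, lay above each CD9low array, from -2.75 to -1.40. The real split gave a difference of 1.45 and the highest of the other splits 1.29, so 1 of the 35 splits gave a difference as large (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). That p holds only if arrays may be exchanged freely. The 8 splits that exchange arrays only within a replicate number are too few to give a share under 0.05. Most of it came from the interstitial list, whose mean differed by 1.21 (1 of 35 splits as large), while the mean of the committed list differed by -0.24 (13 of 35 splits as large). A change of the interstitial markers alone therefore cannot be told apart from a shift in the balance, and the test was run on the data that raised the hypothesis. Icam1, the marker that names the committed state, differed by 0.69 (adjusted p = 0.287), in the direction opposite to the hypothesis. In the balance, CD9low replicate 2 lay closest to the CD9high arrays.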
